A study of Mus musculus with 2 samples.

How the data were processed

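Total RNA of mouse liver was extracted with Trizol and made into sequencing libraries with a SMARTER mRNA-Seq kit, per the labels' protocols. There was 1 library from WT mice with floxed Rcrin alleles and 1 from Rcrin conditional knockout mice. Groups were taken from the genotype label of each sample. The number of mice behind each library, the cells in which Rcrin was deleted, the sex of the mice and the hour of sampling were not given in the sources used here.

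The deposited values were raw read counts per Ensembl gene, per the file headers, as whole numbers with a different total in each library. The submitters' processing notes name the mouse build GRCm38, also called mm10. The aligner, the counting program, the annotation release, the use of strand and the treatment of reads that map to several places were not given in the sources used here. Both tables listed the same 55421 genes. Gene names, positions, exon numbers, transcript lengths and GC content came from GENCODE M21 on GRCm38, in which 55154 of the genes had an entry. The unmatched genes held 0.00541% of the WT counts and 0.00956% of the knockout counts. The exon number of a gene is that of its transcript with most exons, and its length and GC content are medians over its transcripts. No gene in the reference tables carried the name Rcrin or listed it as a synonym, so its level was not analysed here.

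Library totals were 65121596 counts (WT) and 63587567 (knockout). They were scaled with TMM factors from edgeR 4.0.16, 1.02 for WT and 0.982 for the knockout, in R 4.3.3. A read count of 0.5, scaled to library size, was added before the log2 ratio of knockout over WT was taken. Genes were compared if their mean over both libraries was at least 50 counts, and counted as higher or lower at a log2 ratio of at least 1 in size. With 1 library per genotype neither edgeR nor DESeq2 was used for a test, and no standard error or p-value was computed. Each ratio has an exact conditional (Clopper-Pearson) 95% interval, which covers counting error only. Reads made by PCR without molecular identifiers are not independent molecules, so the true counting error is larger. The intervals say nothing of the spread between animals. Where a gene was listed at 0 in 1 library, no fold is given, because genes that every cell uses were among them. List medians that hold such genes were also computed with 0 set to a floor of 3 counts.

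Before the data were examined, 48 gene lists were fixed that cover liver metabolism, acute phase and plasma proteins, zonation, sex-biased genes, stress responses, ribosomes, mitochondria, the clock, handling of tissue and markers of other cell types, blood, neighbouring organs and sex. They held 1223 entries for 1153 genes, of which 1150 matched a name in the reference and 69 stood in more than 1 list. For each list with at least 4 genes compared, the median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn from the same 20 bins of mean expression. A median below the 2.5th or above the 97.5th percentile is called outside the range. Genes of a list are not independent, so the percentile describes these 2 libraries and does not test the genotype.

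Named genes followed a rule fixed in advance. It took the 12 highest and 12 lowest log2 ratios among genes with a mean of at least 100 counts, leaving out predicted genes and bare identifiers. It also took the 4 members farthest in the direction of each list outside the range, at most 2 of the highest members of other lists, and the extremes of the lists of other cell types, sex chromosome markers, clock genes and immediate early genes. Because the first part of the rule gave only genes listed at 0, a further 12 genes in each direction were taken after the values were seen, among genes with at least 4 exons, a mean of at least 1000 counts and counts in both libraries. Some genes that these rules took are not reported here. Genes with close paralogs or pseudogenes can share reads with them, so their values are uncertain, and the main cases are pointed out.

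The calculations were tested on simulated counts for 12049 genes with the real library sizes. Of 200 genes changed in the simulation, 50 in each direction by 4-fold and 50 in each direction by 1.5-fold, all of the former were called (100.0% up and 100.0% down) and 0% of the latter. Of unchanged genes 0% were called. The exact intervals held the true ratio for 95.2% of genes. These figures hold for counting error alone. For the list step a spread with an SD of 0.7 was added between genes and 1000 random lists of the simulated genes were drawn. Of 200 unshifted lists of 25 genes 6.0% lay outside the range, and of 50 lists shifted 1.5-fold 96.0% lay above it.

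Alternatives fixed in advance were DESeq2 1.42.0 size factors, scaling by total count, no level filter, a filter 10 times higher, 5 reads added in place of 0.5, a limit of 4-fold or 1.5-fold, and an exact interval wholly beyond 2-fold. For lists they were random lists not matched on expression, the mean in place of the median, both filters, 5 reads added and the removal of genes in more than 1 list. Chosen after seeing the data were the restriction to genes with at least 3 exons and counts in both libraries, and the removal of the GC trend as the median log2 ratio in 20 bins of GC content, alone and together. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.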

Results

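Mouse liver RNA was sequenced in 2 libraries, 1 per genotype, and the labels do not say whether a library held RNA of 1 mouse or of several. The WT library came from mice with floxed Rcrin alleles, in which loxP sites flank part of the gene and leave it in place. The other library came from Rcrin conditional knockout mice. The labels give a time of 8 weeks for both. The WT library held 65121596 counts and the knockout library 63587567, and 17487 and 17333 genes had a count above 0. The 10 highest genes took 23.2% of the WT counts and 25.2% of the knockout counts. Across the 12064 genes compared, the log2 CPM values of both libraries had a Spearman rho of 0.916, a relation across genes, which are not independent replicates. With 1 library per genotype there was no estimate of the spread between mice. No test was made and no p-value is given, every difference below is one between these 2 libraries, and intervals cover counting error only. The level of Rcrin itself was not analysed here.

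The comparison asked which liver genes differ when Rcrin is depleted. Genes of the acute phase response, red blood cells, neutrophils, macrophages, extracellular matrix and protein folding stood lower in the knockout library than in the WT library. Genes of drug conjugation, ribosomal proteins, oxidative phosphorylation and the immediate early response stood higher. By the fixed limit of 2-fold, 1019 genes were higher and 1039 lower in the knockout library among those with a mean of at least 50 counts. Of 48 gene lists fixed before the data were examined, 19 had a median log2 ratio outside the middle 95% of 10000 random lists matched on expression, 8 above and 11 below. About 5% would lie outside by chance if genes were independent. With the mean in place of the median, 9 of the 48 lists lay outside. The macrophage, matrix, heat shock, unfolded protein and conjugation lists were not among those 9.

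**Figure D1:**
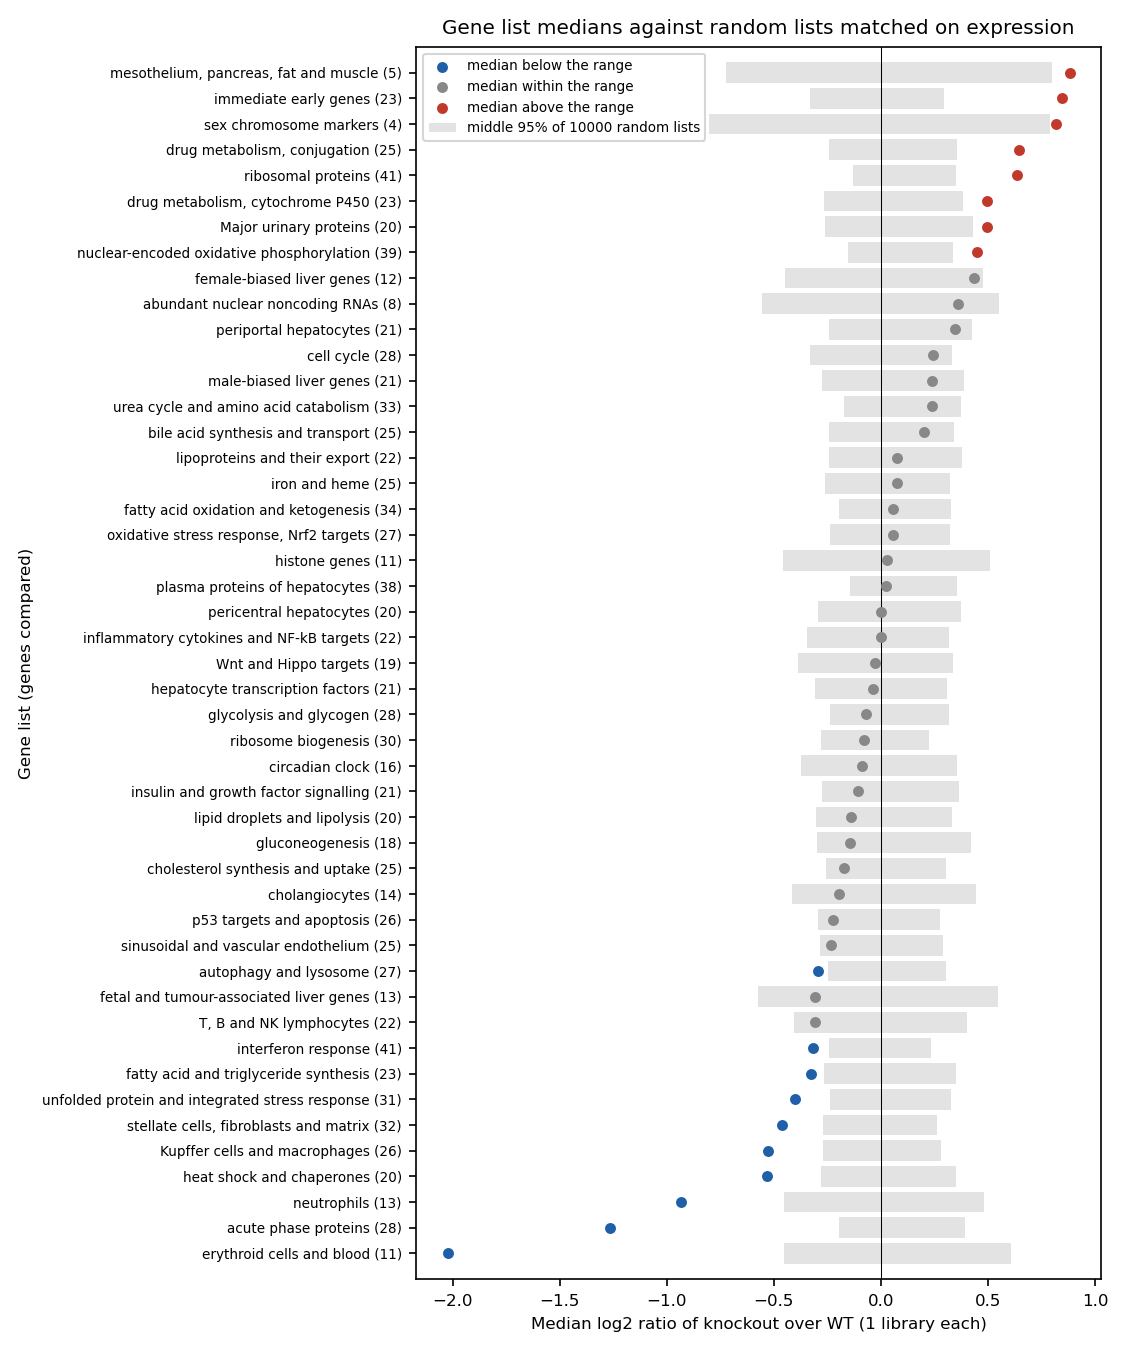
Median log2 ratio of knockout over WT (x axis) for each gene list (y axis, with the number of genes compared), as points, against the middle 95% of 10000 random lists matched on expression, as grey bars. Acute phase, neutrophil and blood genes lie farthest below their bars, and immediate early, conjugation and ribosomal protein genes lie above theirs. The list of mitochondrially encoded genes, in which 3 of 4 members were listed at 0 in 1 library, is left out.

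The acute phase genes, which hepatocytes switch on in inflammation, had a median log2 ratio of -1.26. Of 28 genes compared, 16 were lower by at least 2-fold in the knockout library, 3 were higher and 9 lay between. Serum amyloid A2 (Saa2, ENSMUSG00000057465, GRCm38 chromosome 7 from 46751790 to 46754313) had 465943 counts in the WT library and 4458 in the knockout library, 98.5-fold lower (log2 ratio -6.62, interval -6.67 to -6.58). Its neighbour Saa1 (chromosome 7 from 46740497 to 46742980) had 687950 and 32213 counts, 20.1-fold lower. Reads of these near-identical paralogs can be split between them, so their sum is the firmer value. Together they took 1.77% of the WT counts and 0.0577% of the knockout counts, 29.7-fold lower. Metallothionein 2 (Mt2) was 35.9-fold lower and lipocalin 2 (Lcn2), an iron-siderophore binding protein, 29.3-fold lower. Haptoglobin (Hp) and the fibrinogen alpha chain (Fga), named after their values were seen, were 2.52-fold and 2.36-fold lower. The 3 genes on the other side, named after their values were seen, were the iron hormone hepcidin (Hamp, 1424 and 19400 counts, log2 ratio 3.85), its paralog Hamp2 (log2 ratio 6.17) and C-reactive protein (Crp, 151 and 43791 counts, log2 ratio 8.26). Reads of Hamp and Hamp2 are uncertain between these paralogs. Crp has only 2 exons, Mt2, Hamp and Hamp2 have 3 and Saa1 and Saa2 have 4, and genes with few exons differed widely between these libraries, as described below.

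**Figure D2:**
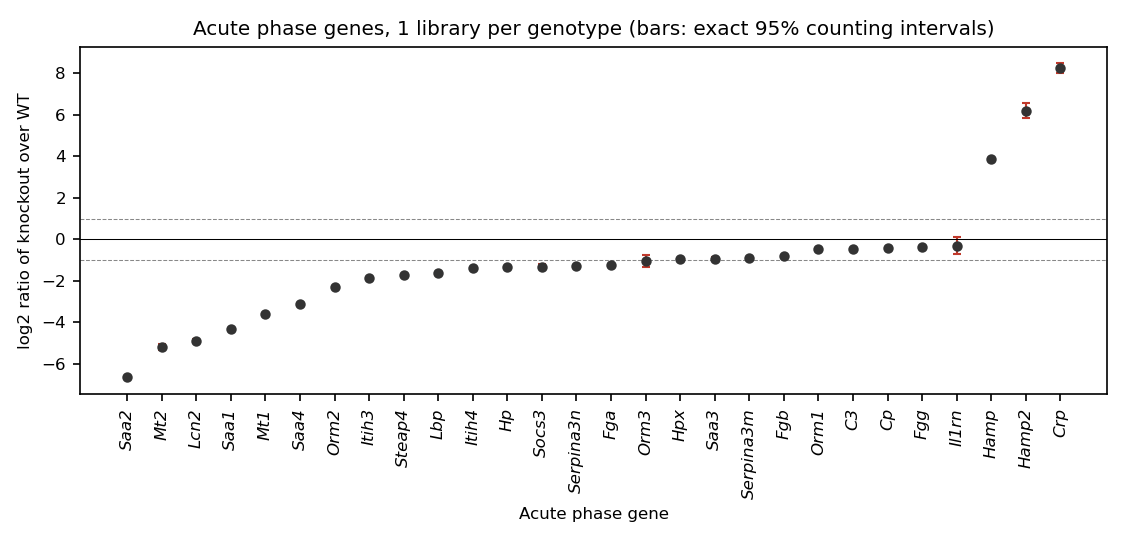
Log2 ratio of knockout over WT (y axis) for the 28 acute phase genes compared (x axis), as points, with exact 95% counting intervals, many of them smaller than the points. Dashed lines mark 2-fold. Saa2 stands lowest at -6.62, and Hamp, Hamp2 and Crp stand apart above 0.

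Markers of blood and neutrophils stood lower beside the acute phase genes. The erythroid and blood list had a median of -2.02 over 11 genes, 6 of them lower by at least 2-fold and 0 higher. The alpha and beta globin genes together took 0.293% of the WT counts and 0.0469% of the knockout counts, 6.02-fold lower. Hba-a2 (log2 ratio -3.30), Hba-a1 (-2.87) and Hbb-bs (-2.51) share reads between paralogs. Each has 3 exons, and genes with few exons differed widely between these libraries, as described below. The red cell anion exchanger Slc4a1, with 20 exons, had 136 and 25 counts (log2 ratio -2.34). Alas2, the erythroid enzyme of heme synthesis, has 11 exons and was the highest of the list at 0.55 (13871 and 19110 counts). The neutrophil list had a median of -0.93 over 13 genes, 6 lower and 2 higher. Lcn2, which also belongs to the acute phase list, led it, followed by the granule genes Mpo (526 and 58 counts, log2 ratio -3.08), Elane (-2.98) and Ltf (-2.72). Interleukin 1 beta (Il1b) went the other way, with 288 and 1278 counts and a log2 ratio of 2.23.

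Macrophage, matrix and interferon genes were lower by less. Kupffer cell and macrophage genes had a median of -0.53 over 26 genes, 5 lower and 1 higher. Trem2 (log2 ratio -1.61), the iron exporter Slc40a1 (-1.40), the lysosomal marker Cd68 (-1.30) and Itgax (-1.17) led, and Vsig4 stood highest at 1.02. Stellate cell, fibroblast and matrix genes had a median of -0.46 over 32 genes (percentile 0.08), 5 lower and 0 higher. Col1a1, a chain of type I collagen, had 945 and 279 counts (log2 ratio -1.67), and Acta2 (-1.49), Col6a1 (-1.31) and Loxl1 (-1.25) followed, with Colec11 highest at 0.67. Interferon response genes had a median of -0.32 over 41 genes (percentile 0.38), 5 lower and 3 higher, led by Oas3 (-1.91), Oasl2 (-1.53), Irgm1 (-1.39) and Oas2 (-1.26). With the mean in place of the median, all 3 lists came inside the range, at percentiles 5.52, 4.97 and 23.7. Their means were -0.49, -0.46 and -0.15, so only the interferon value fell much in size. Medians of T, B and NK lymphocyte genes (-0.31, 22 genes), endothelial genes (-0.23, 25 genes) and cholangiocyte genes (-0.19, 14 genes) lay within the range of random lists. The lymphocyte median was 0.04 without a level filter, the endothelial mean was 0.004, and the cholangiocyte median was 0.09 with the GC trend removed and 0.14 without genes in more than 1 list, so these have no firm direction. Endothelial genes ran from Oit3 at -1.13 to Bmp2 at 2.23, and cholangiocyte genes from Anxa5 at -1.11 to Tstd1 at 2.53.

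Chaperone genes of the cytosol and the endoplasmic reticulum also stood lower. Heat shock genes had a median of -0.53 over 20 genes (percentile 0.02), 4 lower and 0 higher. Hspa1b, which has a single exon, had 12637 and 2734 counts (log2 ratio -2.12). Its near-identical paralog Hspa1a, named after its value was seen, had a log2 ratio of -0.02, so the split of their reads is uncertain. Hspb1 (-1.87), Hsp90aa1 (-1.64) and Hsph1 (-1.09) came next. Genes of the unfolded protein and integrated stress responses had a median of -0.40 over 31 genes (percentile 0.12), 7 lower and 1 higher. Asparagine synthetase (Asns) had 349 and 58 counts (log2 ratio -2.49). The protein disulfide isomerase Pdia4 had 22413 and 4852 counts (-2.12), and Dnajb11 (-1.51) and Creld2 (-1.32) followed. The means of the 2 lists, -0.66 and -0.49, lay inside the range, at percentiles 4.58 and 5.25.

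Drug metabolism genes stood higher in the knockout library. Conjugation genes had a median of 0.64 over 25 genes, 9 higher and 2 lower. The glutathione transferases Gsta1 (27 and 330 counts, log2 ratio 3.67) and Gsta2 (226 and 1976 counts, 3.21), the sulfotransferase Sult1d1 (774 and 2927 counts) and Gsta4 (1.90) led, with reads of Gsta1 and Gsta2 uncertain between paralogs. The mean of the list lay just inside the range, at percentile 97.4. Cytochrome P450 genes had a median of 0.50 over 23 genes (percentile 99.5), 7 higher and 2 lower. Cyp2c37 had 5143 and 25530 counts (log2 ratio 2.40) and Cyp2a5 4454 and 20554 (2.29), and Cyp2b9 (2.10) and Cyp2b10 (1.99) came next. These also belong to families of close paralogs. The P450 median became 0.35 (percentile 96.1) once a trend with GC content was removed and 0.26 (percentile 85.9) without genes that stand in more than 1 list.

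Ribosomal protein genes were higher by a small and even amount. Their median log2 ratio was 0.64 over 41 genes, 39 of them above 0, with 3 past 2-fold and 0 lower by as much. With the GC trend removed 8 were past 2-fold. Rpl30 (log2 ratio 1.14), Rps7 (1.07), Rpl12 (1.03) and Rps14 (0.98) led, and many processed pseudogenes can share their reads. Rpl30 (0.87 with the GC trend removed), like Ndufb3 (0.86) and Uqcrb (0.63) below, came back within 2-fold under that correction. Nuclear-encoded genes of oxidative phosphorylation had a median of 0.45 over 39 genes (percentile 99.8), 34 of them above 0, with 2 higher and 1 lower past 2-fold. Ndufb3 (1.13), Uqcrb (1.06), Atp5h (1.00) and Cox7c (0.94) led. Immediate early genes, which respond within minutes to signals and to handling of tissue, had a median of 0.84 over 23 genes, 11 higher and 2 lower. Egr1 had 618 and 6337 counts (log2 ratio 3.44) and Nr4a1 154 and 890 (2.61). The 1- and 2-exon genes Rhob and Junb were listed at 0 in the WT library, with 2616 and 9486 counts in the knockout library, and Ier2 was listed at 0 in the knockout library, with 1968 counts in the WT library. The median was 0.85 with each 0 set to a floor of 3 counts, and 1.03 over the 14 genes with at least 3 exons and counts in both libraries.

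Lipid synthesis and lysosomal genes lay below the range by small amounts that other settings removed. Fatty acid and triglyceride synthesis genes had a median of -0.33 over 23 genes (percentile 0.64), with 2 lower and 4 higher past 2-fold. The lower ones were Mid1ip1 (log2 ratio -3.02), which has only 2 exons, and the fatty acid elongase Elovl5 (-2.55). Fads2 (-0.99) and Slc25a1 (-0.82) came next. Among members with at least 3 exons and counts in both libraries, 1 was lower and 3 higher past 2-fold. The 4 higher ones, named after their values were seen, were Pnpla3, Srebf1, Acss2 and Thrsp. With the GC trend removed the median was -0.08 (percentile 10.8). Autophagy and lysosome genes had a median of -0.29 over 27 genes (percentile 0.96), 1 lower and 2 higher, led by Lamp1 (-1.50), Map1lc3b (-0.78), Ctsb (-0.68) and Atg14 (-0.60), and became -0.16 (percentile 2.59) with the GC trend removed. Against random lists not matched on expression the median lay at percentile 2.68. By the mean, these lists lay at percentiles 19.6 and 20.8.

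Smaller groups above the range were less firm. Major urinary protein genes, a family of close paralogs, had a median of 0.50 over 20 genes (percentile 99.1), 2 higher and 0 lower, led by Mup21 (1.87), Mup1 (1.09), Mup16 (0.91) and Mup18 (0.91). The median was 0.09 (percentile 41.4) with the GC trend removed, and the mean lay at percentile 96.2. Markers of mesothelium, pancreas, fat and muscle had a median of 0.88 over 5 genes (percentile 98.5) and a mean at percentile 90.3. Car3, which the liver also expresses, stood at 1.92, Cela1 at 1.03, Upk3b at 0.88, Msln at 0.38 and Cela2a at -1.03. Both libraries held counts of Y-linked genes and Xist was listed at 0 in both. The Y-linked genes had a median of 0.82 over 4 genes (percentile 97.9). Ddx3y had 122 and 1219 counts (log2 ratio 3.40), Eif2s3y a log2 ratio of 0.85, Uty 0.78 and Kdm5d 0.57. The median was 0.35 (percentile 87.4) with the GC trend removed, the mean lay at percentile 96.5, and without a level filter the median lay at percentile 97.1.

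The other metabolic lists of hepatocytes did not stand apart from random lists. Plasma protein genes had a median of 0.02 over 38 genes, with albumin (Alb) at 3350104 and 5599153 counts (log2 ratio 0.83) and transferrin (Trf) at -0.93. Medians were 0.06 for fatty acid oxidation and ketogenesis, -0.14 for lipid droplets and lipolysis, 0.08 for lipoproteins and their export, 0.20 for bile acid synthesis and transport, -0.14 for gluconeogenesis and -0.07 for glycolysis and glycogen. They were 0.24 for the urea cycle and amino acid catabolism, -0.11 for insulin and growth factor signalling, 0.07 for iron and heme and 0.06 for Nrf2 targets. Pericentral hepatocyte genes had a median of 0.00 and periportal genes one of 0.35, with Cyp2e1 at 0.50 and Glul at -0.18 in the first. Cholesterol synthesis and uptake genes had a median of -0.17 (percentile 9.90). With the GC trend removed they moved below the range, to -0.28 (percentile 0.28). Male-biased liver genes had a median of 0.24, which moved above the range, to 0.42 (percentile 98.4), with the same correction. Female-biased liver genes had a median of 0.43 (percentile 96.4).

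The remaining lists also lay within the range. Medians were -0.04 for hepatocyte transcription factors, -0.31 for fetal and tumour-associated liver genes, -0.00 for inflammatory cytokines and NF-kB targets, 0.24 for the cell cycle and -0.22 for p53 targets and apoptosis. They were -0.08 for ribosome biogenesis, 0.03 for histone genes, 0.36 for abundant nuclear noncoding RNAs and -0.03 for Wnt and Hippo targets. Circadian clock genes had a median of -0.09 over 16 genes, 4 higher and 0 lower, from Nfil3 at -0.78 to Nr1d1 at 2.18 (179 and 765 counts). Members of this list peak at different hours, so their median cannot show whether both libraries were sampled at the same hour.

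The most extreme values of all came from genes listed at 0 in 1 library. By the fixed rule, the 12 lowest included mt-Nd2, Pcbp1, Cldn3, mt-Co1, mt-Nd4, Atxn7l3b, Tob1, H2afx, Hnrnpa0, Imp3 and Irf2bp1, each listed at 0 in the knockout library. The 12 highest were Junb, Mgat2, Rhob, Sdhaf1, Eno1b, Gdf2, Sap18b, Rraga, Nup62, Dolk, Clec14a and C1galt1c1, each listed at 0 in the WT library. Each of them has 1 or 2 exons. Of 354 genes with 1 exon, 30.8% were listed at 0 in 1 library, and of 11208 genes with at least 3 exons, 0.125%. Zeros also stood among the 13 mitochondrially encoded protein genes, which every liver cell uses. Of these, 9 were listed at 0 in the WT library and 12 in the knockout library, 9 of them in both. Of the 4 that could be compared, only mt-Cytb had counts in both libraries (255139 and 376551), and the median of -13.7 (-11.0 with each 0 set to 3 counts) carries no fold. Differences over 8-fold made up 16.1% of genes with 2 exons, 4.32% with 3 exons, 3.82% with 4 exons and 0.383% with at least 21 exons.

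**Figure D3:**
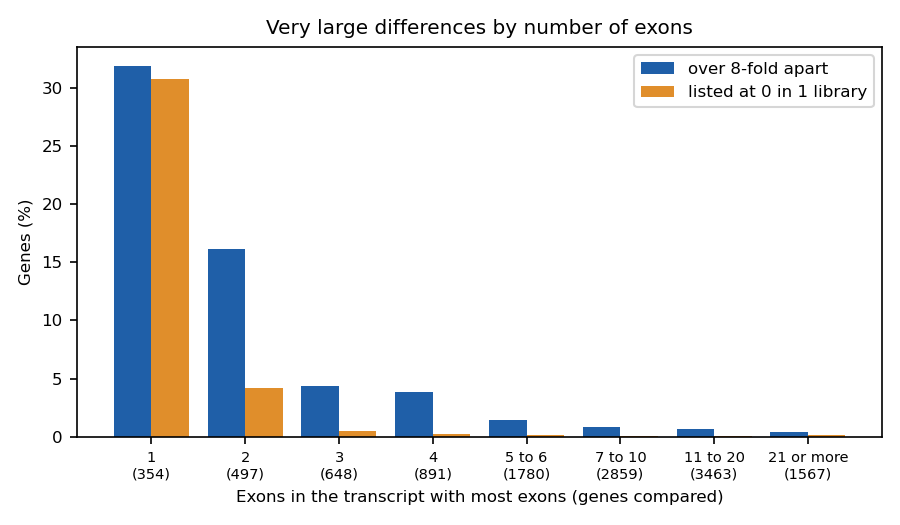
Share of genes compared, in percent (y axis), that differed over 8-fold between the libraries (blue) or were listed at 0 in 1 library (orange), by the number of exons (x axis, with the number of genes). The shares are 31.9% and 30.8% for genes with 1 exon and 1.23% and 0.125% for all genes with at least 3 exons.

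Among genes with at least 4 exons, a mean of at least 1000 counts and counts in both libraries, a rule set after the values were seen, the lowest 12 again held Saa2, Lcn2, Saa1 and Saa4. The immunoglobulin genes Ighg1 (log2 ratio -4.84) and Ighg2b (-3.35) stood among them, as did Cmtm6, a membrane protein gene (9300 and 323 counts, -4.76), Rgp1 (-3.60), Mrps2 (-3.40), Tubb5 (-3.37) and Sfxn2 (-3.19). The highest were Sptssa, a subunit of the enzyme that starts sphingolipid synthesis (76 and 2281 counts, log2 ratio 4.98), sulfite oxidase (Suox, 631 and 15179 counts, 4.67), Rnf11 (4.41) and the retinol dehydrogenase Rdh16 (373 and 5653 counts, 16.1-fold higher). Pid1 (3.84), Gsta2 (3.21), the glucuronosyltransferase Ugt2b34 (3.17), Apol7a (3.04), Cmah (387 and 2919 counts), Tubb2a (2.98), Ube2g1 (2.81) and Fads6 (2.71) followed. Values of the immunoglobulin, tubulin, Gsta2, Ugt2b34, Apol7a and Saa genes are uncertain between paralogs. With genes of 1 or 2 exons and those listed at 0 left out, 855 genes were higher and 853 lower by at least 2-fold among 11194.

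The log2 ratio also followed the GC content of transcripts. Over the 11194 genes with at least 3 exons and counts in both libraries, Spearman's rho was -0.346 across genes. The median log2 ratio was 0.43 in the eighth of genes with the lowest GC content and -0.26 in the eighth with the highest. With this trend removed, the acute phase median was -1.14, the ribosomal protein median 0.70 and the oxidative phosphorylation median 0.51, all still outside the range of random lists.

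**Figure D4:**
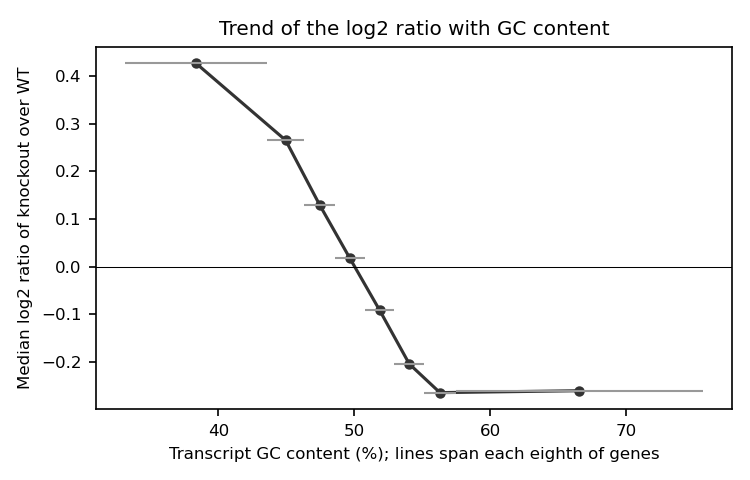
Median log2 ratio of knockout over WT (y axis) in 8 equal groups of genes by transcript GC content in percent (x axis), drawn at the middle of each group's span, with lines over the span. Medians run from 0.43 in the lowest group to -0.26 in the highest.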

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

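The exon filter and the GC correction were chosen after seeing the data. The counts of 1019 higher and 1039 lower genes moved by more than 1.5 times under 4 settings. Without a level filter there were 3366 and 3556 among 19111 genes, and with a filter 10 times higher 452 and 465 among 7217, since these settings change how many genes enter. At a limit of 4-fold there were 303 and 338, and at 1.5-fold 2289 and 2267. The other settings gave 715 to 1002 higher and 745 to 1145 lower genes, and the share of higher genes among the calls ran from 44.5% with total count scaling to 50.2% over all settings. Total count scaling moved the median of all genes from -0.01 to -0.06. With the GC trend removed, 797 of the 921 higher and 856 of the 969 lower genes were among the main ones.

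Of the 48 lists, 19 lay outside the range, and 9 with the mean in place of the median, 8 of them in the same direction. The cause was not tested. Those 8 were acute phase, neutrophil, blood, immediate early, ribosomal protein, oxidative phosphorylation, P450 and mitochondrially encoded genes, and the 9th was histone genes. Of the 11 histone genes compared, 4 were listed at 0 in 1 library, so their mean of 1.21 (median 0.03) carries no fold. The other settings gave 16 to 20 lists, with no list called in the opposite direction. Of the 29 lists within the range, 18 changed the sign of their value under at least 1 setting, and of the 19 outside it 0 did. Among lists that came outside under some of them were endothelial genes below the range with the higher filter (-0.38, percentile 1.17), and female-biased genes (0.60, percentile 98.7) and nuclear noncoding RNAs (0.83, percentile 99.5) above it without a filter. With the exon filter these 2 lay at percentiles 97.53 and 97.8, and with the exon filter and GC correction together the cell cycle list lay at 97.9. The acute phase, neutrophil, blood, immediate early, ribosomal protein and oxidative phosphorylation lists kept their side under every setting run. Of 179 values of named genes, the GC correction took 10 back within 2-fold and moved 2 past it, and none changed sign past the limit. The level of Rcrin under another scaling was not run, because the gene was not matched. No paired analysis was possible because there was 1 library per genotype. Depth limited some named genes, since the counting intervals of Itgax (-1.64 to -0.73), Loxl1 (-1.61 to -0.90) and Cela2a (-1.42 to -0.67) crossed 2-fold, and the spread between mice could not be estimated.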

Other observations

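The tests below were chosen after their results had been seen, apart from the one on transcript length. Immunoglobulin genes, which plasma cells transcribe, were mostly lower in the knockout library. The 4 IgG constant genes together had 8320 counts in the WT library and 801 in the knockout library, 9.79-fold lower (log2 ratio -3.29, counting interval -3.40 to -3.19). Of 21 immunoglobulin variable segments with enough counts, all 21 had a log2 ratio below 0 and 20 were lower by at least 2-fold, with a median of -3.12. The joining chain Jchain had 2311 and 473 counts. The kappa constant gene Igkc went against them, with 25 counts in the WT library and 1666 in the knockout library. It has a single exon, but the limit of few exons was not checked for the variable segments either. Those segments can share reads, so they are not 21 separate observations. Immunoglobulin genes are close paralogs, so the split of reads among them is uncertain.

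Some further genes with differences over 2-fold were chosen after their values were seen. Among all genes compared, 36.0% of those with 2 exons, 28.2% with 3 and 20.9% with 4 differed by at least 2-fold. Fabp1 has 4 exons. Exon number was not weighed in choosing the genes named here, so values of those with few exons are not firm. Apolipoprotein A-IV (Apoa4) had 29053 counts in the WT library and 5270 in the knockout library, 5.20-fold lower. The lipogenic transcription factor gene Srebf1 was 2.93-fold higher, the fatty acid binding protein Fabp1 2.56-fold and the fatty acid transporter Cd36 3.04-fold. The secreted factors Igfbp1 and Gdf15 were 4.01-fold and 3.19-fold higher. The interleukin 6 receptor gene Il6ra had 1150 and 172 counts and the NF-kB subunit Rela 5200 and 1309. The list of inflammatory cytokines and NF-kB targets, which holds Rela, had no shift as a set. Its median was -0.002 over 22 genes (percentile 53.7), 4 higher and 6 lower past 2-fold.

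Genes that the liver uses were listed at 0. Of the 144 compared genes listed at 0 in 1 library, 130 (90.3%) had at most 2 exons, against 7.05% of all genes compared, as would be seen if the counting of genes with 1 or 2 exons had failed. Of these 130 genes, 51.5% were at 0 in the WT library and the rest in the knockout library. The 9 mitochondrially encoded protein genes at 0 in the WT library were also at 0 in the knockout library. Zeros that the WT library shares argue against loss of Rcrin as their cause. For genes at 0 in 1 library only, a role of Rcrin cannot be told apart from the counting. Each genotype has 1 library, and the counting program is not known.

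Ribosomal protein and oxidative phosphorylation genes were higher in the knockout library, with medians of 0.64 and 0.45. The GC content trend between the libraries does not account for this, since genes of the GC content of these lists had medians of -0.20 and 0.018. The transcript length trend was not the whole cause. These transcripts are short, with median lengths of 681 and 635 bases, but against random lists matched on length the lower list still lay at percentile 99.81. Differences between the mice or their libraries other than these trends stay open, and so does the genotype, which was not tested.

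Acute phase genes were lower in the knockout library, with a median of -1.26. The counting of genes with few exons was not the whole cause, because the 18 members with at least 5 exons had a median of -1.14, with 10 lower and 0 higher past 2-fold. More blood in the WT sample would dilute hepatocyte RNA there, yet the 19 members made mainly by hepatocytes had a median of -1.24. An acute phase reaction in the WT sample, whatever its genotype, cannot be told apart from an effect of Rcrin with 1 WT library. The members Hamp, Hamp2 and Crp went the other way.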
